A study of Mus musculus with 10 samples.

How the data were processed

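Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 10 libraries from frozen liver tumours of FVB mice. In these mice a tetracycline-controlled activator under a liver promoter (LAP, from Cebpb) drives a MYC transgene once doxycycline is withdrawn. The labels give 3 groups by Arid1a genotype. WT tumours (n = 4, about 55 days) carried floxed Arid1a without Cre. Het tumours (n = 3, about 70 days) carried 1 floxed allele with Cre under the albumin promoter, and Homo tumours (n = 3, about 100 days) carried 2 floxed alleles with it. Groups were taken from the sample titles. Age rises with the number of floxed alleles exposed to Cre, so age and genotype cannot be separated here. Cre was absent from all WT and present in all Het and Homo tumours. An effect of Cre itself therefore cannot be separated from Arid1a genotype in comparisons with WT. The titles number the replicates but do not say that each came from a separate mouse, so the p-values measure the spread between these libraries.

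The authors deposited 1 narrowPeak list per library. Reads were aligned with Bowtie2 to mm10, peaks were called with MACS2 and deepTools was used, per the submitters' processing notes, which give no versions. Peak calling settings, read filters, the shift of reads for the transposase and the number of reads are not given in the sources used here. Each deposited row gives a score, which equals 10 times the −log10 p cut to a whole number in nearly all rows. The deposited fold (a ratio) is the pileup of tags at the summit plus 1 over the local background plus 1. The deposited −log10 p and −log10 q values come from the same pileup. The smallest −log10 p in the lists lay between 5.00 and 5.63, which fits a p threshold of 1e-05. These per-peak values are the authors' own and were used here to rank, filter and thin peaks within a list. Peaks were called per library, so a region can be present or missing in each replicate, and no read counts per region were analysed here.

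Sequencing depth was recovered from the lists. In each row a whole-number pileup and a Poisson background that together give the deposited fold and −log10 p were sought, with a tolerance of 0.001 in −log10 p, and were found for 100% of the rows of each of the 10 lists. The smallest background shared by at least 10 rows, in tags per 200 bp, was taken as the depth of the library. It was derived from the lists and was not checked against the total number of reads, which is not given. It ranged from 0.465 in Homo 2 to 1.74 in WT 1, a 3.76-fold range. A deeper library gives more peaks, so depth-matched lists were also made. Every summit pileup was thinned at random to the background of Homo 2, and peaks with −log10 p of at least 5 were kept. Counts come from 1 seeded draw, and the numbers of peaks also from 20 draws. This alternative was chosen after seeing the data, as were lists equal in depth, number and width, made of the 1748 strongest thinned peaks as summits with 100 bp on each side.

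Rows that overlapped or touched were merged into distinct regions, and autosomes and X were used. Regions were placed against 21887 protein-coding genes of the RefSeq table for GRCm38.p6, whose primary coordinates are those of mm10. The table has gene starts and ends but no strand, exons or UTRs. The promoter window planned around the transcription start was replaced by 1000 bp on each side of either gene end (gene-end peak), and the other classes are gene body and intergenic. Of 387 entries in 19 gene lists fixed before the data were examined, 385 were found in the table. The 16 planned motif counts in distal peaks need a genome sequence, which was not used here, and were not run.

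Peak number, covered length and gene-end share were compared by exact permutation of the group labels, two-sided on the difference of means. With 4 against 3 libraries there are 35 splits and the smallest p is 0.0286. With 3 against 3 the smallest p is 0.1, so Homo against Het cannot pass 0.05. A trend over 0, 1 and 2 floxed alleles exposed to Cre used all 4200 arrangements of the 10 libraries. Benjamini-Hochberg adjustment covered the 9 pairwise tests of these 3 measures. Similarity was the base-pair Jaccard index (shared over combined length), tested one-sided by exact permutation as mean within minus mean between groups. Region presence was counted over the union of all lists, with an overlap of at least 1 bp. A pattern such as WT-only against Homo is a region called in every WT library and in no Homo library. For each gene list the number of members with a gene-end peak was tested by the same exact permutation, adjusted over the 19 lists, and also as a log2 ratio to the share over all other genes, with 0.5 added to each count. The share of the list is given as a percent of its members in the table.

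Genes were named by a rule fixed before the data were examined. Arid1a came first, then Alb, Cebpb and Myc, whose sequences the transgenes share. Then came up to 15 genes each way for Homo against WT, up to 10 each way for the other comparisons and 5 distal regions, ordered by median rank percentile of −log10 p within the lists of the group that holds them. For each gene list, 2 to 4 members with the largest difference in the share of libraries were named. The alternatives tried were −log10 q of at least 5, lists of 1748 peaks each, all sequences, deposited rows, wider gene windows (2500 bp, or the gene body with 10 kb), other definitions of overlap, leaving out each library and pairing by replicate number. Binomial intervals for single libraries cover counting error only. The regions and tests were also tested on simulated data. Of 9526 simulated regions, 200 were closed in simulated Homo libraries at the real depths. Regions and signal came from WT 1 and were otherwise the same in every simulated library. Of these 200, 167 were found as WT-only against Homo, along with 36 regions that were not closed and differed by depth and the random draw of tags. After depth matching the search found 47 of the 200 and 38 others. Simulated WT libraries had 1.31 times as many peaks as Het libraries from depth alone, and 1.01 times after depth matching. Under no effect, 4.60% of simulated trend tests gave p of 0.05 or less. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.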

Results

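The ATAC-seq peak lists covered 10 libraries from liver tumours driven by MYC, with 4 WT, 3 Het and 3 Homo libraries with respect to Arid1a, which encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex. The series asks what loss of Arid1a does in liver cancer, and this part asks how it changes open chromatin. The lists held between 1748 (Homo 2) and 9587 (Homo 3) distinct regions on autosomes and X. Depth, as background tags per 200 bp, was 1.32 ± 0.334 in WT (SD, n = 4), 0.696 ± 0.0416 in Het (n = 3) and 0.995 ± 0.576 in Homo (n = 3). All lists together gave 12266 regions, of which 647 were called in all 10 libraries and 2333 in 1 library. At least 1 library had a gene-end peak at 9218 of 21887 protein-coding genes.

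Arid1a itself (mm10, chromosome 4, 133679008 to 133756769) had a peak inside the gene, near its higher coordinate, in 4 of 4 WT, 2 of 3 Het (Het 1 and Het 3) and 1 of 3 Homo libraries (Homo 3). In WT 1 it spanned 133754054 to 133754549 with a fold of 5.64, and in Homo 3 it spanned 133754196 to 133754567 with a fold of 6.88. Homo 1 instead had a peak at 133757130 to 133757427, and Homo 2 had none within 10 kb of the gene. As far as the labels tell, these peaks cannot be placed in or out of the floxed part, so they do not check the deletion. Cebpb, a liver transcription factor whose promoter drives the activator transgene, had 2 peaks within 10 kb in each of the 10 libraries. Alb, the gene of serum albumin, had a peak at its lower coordinate in WT 2 (90460737 to 90460978, chromosome 5) and in Homo 3 (90460694 to 90460971) and in none of the other 8. The Myc gene (chromosome 15, 61985341 to 61990361) had a peak in its body in WT 4 and Homo 1. Because the transgenes share sequence with Cebpb, Alb and Myc, peaks at these genes cannot be assigned to the endogenous genes alone.

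Homozygous loss was compared with WT to ask which regions are open with Arid1a and closed without it. Gene-end peaks were called in 4 of 4 WT and 0 of 3 Homo libraries at 28 genes, and in the reverse pattern at 1 gene. The WT-only genes ranked highest included Cklf (a chemokine-like factor), Ramac (a cofactor of mRNA cap methylation), Klc3 (a kinesin light chain), Haspin (a mitotic histone H3 kinase) and Dynlt1f (a dynein light chain). Others were Anks3, Capn5 (a calpain protease), Mrpl1 (a mitochondrial ribosomal protein), Tmem231 (a protein of the ciliary transition zone), Nans (sialic acid synthase) and Rad18 (a ubiquitin ligase of DNA damage tolerance). A region at the ends of both Htd2 and Rpp14 (chromosome 14, 8080201 to 8080648) had the same pattern. The 1 gene with peaks in all 3 Homo and no WT library was AW209491 (chromosome 13, 14630245 to 14638202), whose peak at 14630057 to 14630538 was also missing from the 3 Het lists.

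The Cklf peak lay at chromosome 8, 104250724 to 104251087, across the lower coordinate of the gene, and was missing from all 6 Het and Homo libraries. Its median rank percentile in the WT lists was 69.0, the highest of the 28 genes, and at equal depth it was called in 2 of 4 WT libraries and 0 of 6 others. The Nans peak (chromosome 4, 46489065 to 46489593) was called in 4 of 4 WT libraries and 0 of 6 others. With lists thinned to equal depth it stayed in 4 of 4 WT libraries. Thinning and shortening lists only remove peaks, so the 0 of 6 was fixed beforehand and only WT counts could change. Anks3 (chromosome 16, peak 4964056 to 4964721) and Capn5 (chromosome 7, peak 98178013 to 98178360) stayed in 3 of 4 WT libraries and 0 of 6 others at equal depth. Rad18 (chromosome 6, peak 112696281 to 112696795) and Mrpl1 (chromosome 5, peak 96209901 to 96210271) stayed in 2 of 4 and 0 of 6. Among the 1748 strongest peaks of each list, Cklf was called in 2 of 4 WT libraries and Anks3 in 1 of 4. Nans, Capn5, Mrpl1 and Rad18 were called in 0 of 4, so the differences at these genes lie among weaker peaks. Klc3 and Haspin were called in 2 of 3 Het libraries and in 0 of 3 Homo libraries.

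Counted as regions, 35 were WT-only and 2 were Homo-only. Data simulated at the depths of these libraries, with tags drawn at random, gave 36 WT-only regions that were not closed by design and 1 Homo-only region. After thinning to equal depth they gave 38 WT-only regions other than those closed by design, so the 36 cannot be credited to depth alone. Outside the closed regions each simulated library had the signal of WT 1, so the shortfall of Homo 1 and Homo 2 at equal depth was left out. These counts therefore do not show how much of the 35 depth accounts for. Of the 35, 25 lay at gene ends, 7 in gene bodies and 3 between genes. The distal ones ranked highest lay inside Mcmbp (chromosome 7, 128699896 to 128700167), Myo5a (chromosome 9, 75071117 to 75071761), Tpst1 (chromosome 5, 130079316 to 130079777) and Zbtb20, a repressor of fetal liver genes (chromosome 16, 43069890 to 43070223). Another lay 116864 bp from Nudt4 on chromosome 10. The Myo5a region was called in 3 of 3 Het libraries and each of the others in 1 of 3. The second Homo-only region was intergenic, at chromosome 15, 60141794 to 60142042. In WT the 35 regions were weak, with a median rank percentile of 35.9. The 1016 regions called in all WT and all Homo libraries had 79.8, but being called in every library itself selects strong regions. A single region tested by Fisher's exact test cannot go below p = 0.0286 with 4 against 3 libraries, so no region passes an adjustment over all regions. The 35 WT-only regions became 2103 without Homo 3, 67 without Homo 1, 53 without WT 1, 64 without WT 2 and 118 without WT 3, and 125 with lists of equal depth; the 2 Homo-only regions became 7 without Homo 1, 30 without Homo 2, 7 without Homo 3 and 8 at equal depth.

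Peak numbers were 8276 ± 1155 in WT (SD, n = 4) and 5066 ± 4056 in Homo (n = 3). The difference of -3210 was smaller than the Homo spread (exact permutation p = 0.257, adjusted 0.514). It was -5470 without Homo 3 and -1550.5 without Homo 2. With lists thinned to equal depth, WT had 5096 ± 532 and Homo 3388 ± 2087 regions, a difference of -1708 (exact permutation p = 0.2). Covered length was 3.30 ± 0.563 Mb in WT and 2.01 ± 1.91 Mb in Homo (exact permutation p = 0.286), a difference of -1.29 Mb that became -2.37 without Homo 3 and -0.537 without Homo 2. Homo 1 and Homo 2 had 3863 and 1748 regions, while Homo 3 had 9587, more than any WT library. Of 5179 regions called in all 4 WT libraries, Homo 3 held 98.3%, Homo 1 52.6% and Homo 2 26.7%. Gene-end peaks made up 75.7% ± 3.33 of regions in WT and 73.6% ± 3.61 in Homo (exact permutation p = 0.457), a difference smaller than the spread within groups. By counting error alone, the 95% Wilson interval of this share was 67.9% to 72.2% in Homo 2 and 70.8% to 72.6% in WT 1.

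**Figure D1:**
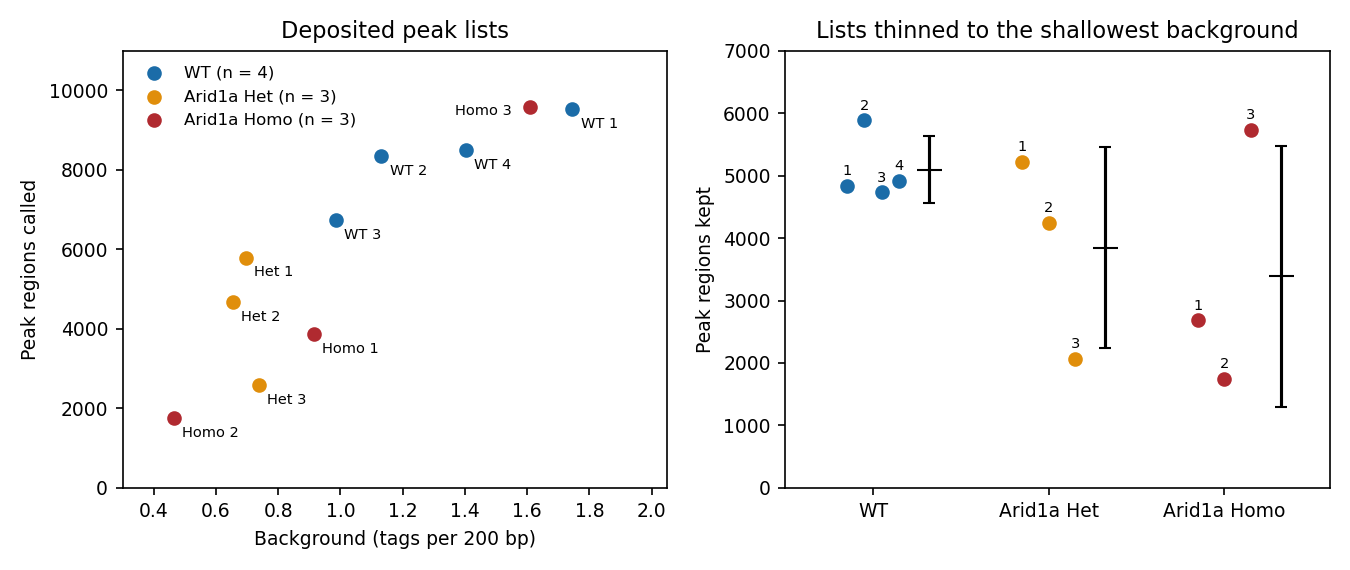
Left, distinct peak regions against background depth (tags per 200 bp), with 1 point per library coloured by Arid1a genotype. Right, regions kept after thinning every list to the background of Homo 2, with points numbered by replicate and black bars for the group mean ± SD; Het 3, Homo 1 and Homo 2 keep 2070, 2680 and 1748 regions, and the WT libraries 4738 to 5887.

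Heterozygous loss was compared with WT to ask whether 1 floxed allele exposed to Cre is enough to change accessibility. Here 475 genes had gene-end peaks in 4 of 4 WT and 0 of 3 Het libraries, and 1 gene, Kif13a (a kinesin motor), had the reverse. The WT-only genes ranked highest were Mid1 (a microtubule-associated ubiquitin ligase), Tada1 (a subunit of the SAGA coactivator), Diablo (a mitochondrial promoter of apoptosis), 1700030J22Rik and Ubn1 (a subunit of the HIRA histone chaperone). Next came Dyrk1b, Fbl (the nucleolar methyltransferase fibrillarin), Copb2 (a coatomer subunit), Tuft1 and Tmem218. Dyrk1b and Fbl share a region at chromosome 7, 28179735 to 28180246, and have the same rank percentile, 79.9. Mid1 (chromosome X, peak 169991191 to 169991616) had a median rank percentile of 93.8 in the WT lists, and Tada1 (chromosome 1, peak 166378781 to 166379653) of 91.1. All 10 of these genes also had a peak in at least 1 Homo library, and Ubn1 and Tmem218 in 2 of 3. Homo 3 held 98.3% of the regions called in all 4 WT libraries. A peak in 1 Homo library was therefore likely for any such gene and says little about Homo tumours.

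At equal depth the Diablo peak (chromosome 5, 123523968 to 123524611), the 1700030J22Rik peak (chromosome 8, 116978625 to 116979165) and the Tuft1 peak (chromosome 3, 94658619 to 94659095) stayed in 4 of 4 WT and 0 of 3 Het libraries. Mid1, Tada1, Ubn1, Copb2 and Tmem218 stayed in 3 of 4 WT libraries, and Dyrk1b and Fbl in 2 of 4. The 0 of 3 Het could not change, since thinning and shortening lists only remove peaks. Among the 1748 strongest peaks of each list, Mid1 was called in 4 of 4 WT libraries, Tada1, Diablo and Tuft1 in 3 of 4 and 1700030J22Rik in 2 of 4, each with 0 of 3 Het. The Kif13a peak (chromosome 13, 46929602 to 46930530) was weak, at a median rank percentile of 7.76 in the Het lists, and was called in 2 of 3 Homo libraries. Among the fixed lists, the WT-only genes were Fbl, Nop58 and Polr1b of the MYC-regulated growth genes, Mcm3 of the cell cycle genes, Smarcd1 and Actl6a of the SWI/SNF subunits, Fosb of the immediate early genes, and Rps18 and Psmb2 of the housekeeping genes. No list was over-represented among the 475 genes against the 5067 genes with a gene-end peak in all 4 WT libraries. The smallest Fisher's exact p was 0.184, for 3 of 16 MYC-regulated genes (adjusted p = 1).

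As regions, 498 were WT-only and 1 was Het-only, and 406 of the 498 lay at gene ends. Het lists had 4348 ± 1630 regions (SD, n = 3) against 8276 ± 1155 in WT (n = 4), a difference of -3927 with every Het library below every WT library (exact permutation p = 0.0286, the smallest possible, adjusted 0.129). Covered length was 1.43 ± 0.588 Mb in Het and 3.30 ± 0.563 Mb in WT (exact permutation p = 0.0286, adjusted 0.129). The gene-end share was 77.2% ± 1.73 in Het and 75.7% ± 3.33 in WT (exact permutation p = 0.514). Background depth differed in the same direction, at 0.696 in Het and 1.32 in WT (exact permutation p = 0.0571), and with lists thinned to equal depth the peak numbers were 3846 ± 1613 and 5096 ± 532 (exact permutation p = 0.200). At equal depth 90 regions were WT-only and 18 Het-only, and with 1748 peaks per list 34 and 32. The 498 WT-only regions became 1258 without Het 1, 857 without Het 2 and 975 without WT 3, and the 1 Het-only region became 2 without WT 1 or WT 4, 5 without Het 1, 6 without Het 2 and 10 without Het 3.

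Homo and Het tumours were compared to ask whether loss of the second allele adds to the loss of the first. Gene-end peaks in 3 of 3 Homo and 0 of 3 Het libraries were found at 30 genes. They were led by Fars2 (a mitochondrial tRNA synthetase) and Lyrm4 (an iron-sulfur cluster protein), which share a region at chromosome 13, 36117295 to 36118016, followed by Gm49894, AW209491, Lyrm2, Arhgap30, Micu3 (a mitochondrial calcium uptake protein), Agpat3, Zfp296 and Fam222a. Fars2, Lyrm4, Gm49894, Arhgap30 and Micu3 also had peaks in 4 of 4 WT libraries. The reverse pattern held at 3 genes, Gm32584, Mboat2 and Kif21b (a kinesin motor). Gm32584 (chromosome 5, 36630163 to 36661658) was called in 3 of 4 WT libraries as well, at a median rank percentile of 95.6 in the Het lists.

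In regions, 32 were Homo-only and 8 Het-only, and with lists of equal depth 21 and 84. The sum of 40 became 120, 78 and 79 without Het 1, Het 2 and Het 3, and 124, 315 and 338 without Homo 1, Homo 2 and Homo 3. Homo and Het lists differed by 718 regions on average, far below the spread within either group (exact permutation p = 0.900, where 0.1 is the smallest possible). Without Homo 3 this difference was -1543 and without Het 3 it was -165. Across all 3 genotypes the slope of peak number was -1706 regions per floxed allele exposed to Cre (exact permutation p = 0.122). With lists of equal depth the slope was -871 (exact permutation p = 0.138). In the deposited lists without Homo 3 it was -2878 (exact permutation p = 0.00397).

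WT libraries were also set against all 6 Het and Homo libraries. At 14 genes a gene-end peak was called in 4 of 4 WT and in 0 of 6 others, and at 0 genes the reverse. Besides Cklf, Anks3, Capn5, Mrpl1, Nans and Rad18, they included Atp6v1h (a subunit of the vacuolar proton pump; chromosome 1, peak 5082951 to 5083477), Tigd3 (chromosome 19, peak 5894002 to 5894360) and a region at the ends of both Maip1 and Tyw5 (chromosome 1, 57406416 to 57407029). In regions the counts were 16 and 0, with 17 and 0 at equal depth and 7 and 1 with 1748 peaks per list. At equal depth Nans was the 1 of these 10 named genes still called in 4 of 4 WT libraries, and the others were called in 1 to 3 of 4, while among the 1748 strongest peaks of each list Nans was called in 0 of 4. The 16 became 361 without Homo 3, 73 without WT 3, 31 without WT 2, and 26 without WT 4 or without Het 1, and the 0 became 1 without WT 4 or without Homo 2.

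Gene lists fixed beforehand showed which functions had gene-end peaks called in these tumours. A missing peak does not show a closed gene end, since the housekeeping genes Actb and Hprt had none in any library. In WT, 78.1% of the housekeeping genes, 76% of the MYC-regulated growth genes, 73.8% of the SWI/SNF subunits, 66.7% of the immediate early and stress genes and 62% of the cell cycle genes had a gene-end peak on average. Lists of liver functions, which were not tested against other lists, had 43.5% for glucose and lipid metabolism, 30% for amino acid and urea cycle metabolism, 28% for liver transcription factors, 22.7% for secreted proteins and 6% for cytochrome P450 and drug metabolism, where Gstm1 and Fmo5 were the 2 members with a peak in any library. Relative to all other genes of the same WT libraries, these were log2 values of 0.41, -0.13, -0.17, -0.57 and -2.11. Metastasis-restraining genes stood at 36.2%, migration and invasion genes at 14.8%, and fetal liver genes at 11.8%, through Epcam (2 of 4 WT), Sall4 (3 of 4), Igf2bp3 (2 of 4) and Dlk1 (1 of 4).

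Markers of other cell types had few peaks within 1 kb of a gene end. Endothelial, stellate cell and fibroblast, and lymphocyte and neutrophil markers had 0 members with a gene-end peak in any of the 10 libraries, though within 2500 bp some endothelial and lymphocyte markers had peaks in WT libraries. Macrophage and Kupffer cell markers had 1, Spi1, in Homo 3. Erythroid markers had Nfe2 in WT 1, WT 2 and Homo 3, and cholangiocyte markers had Epcam in WT 3 and WT 4 and Onecut1, which is also on the liver transcription factor list, in Homo 3.

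**Figure D2:**
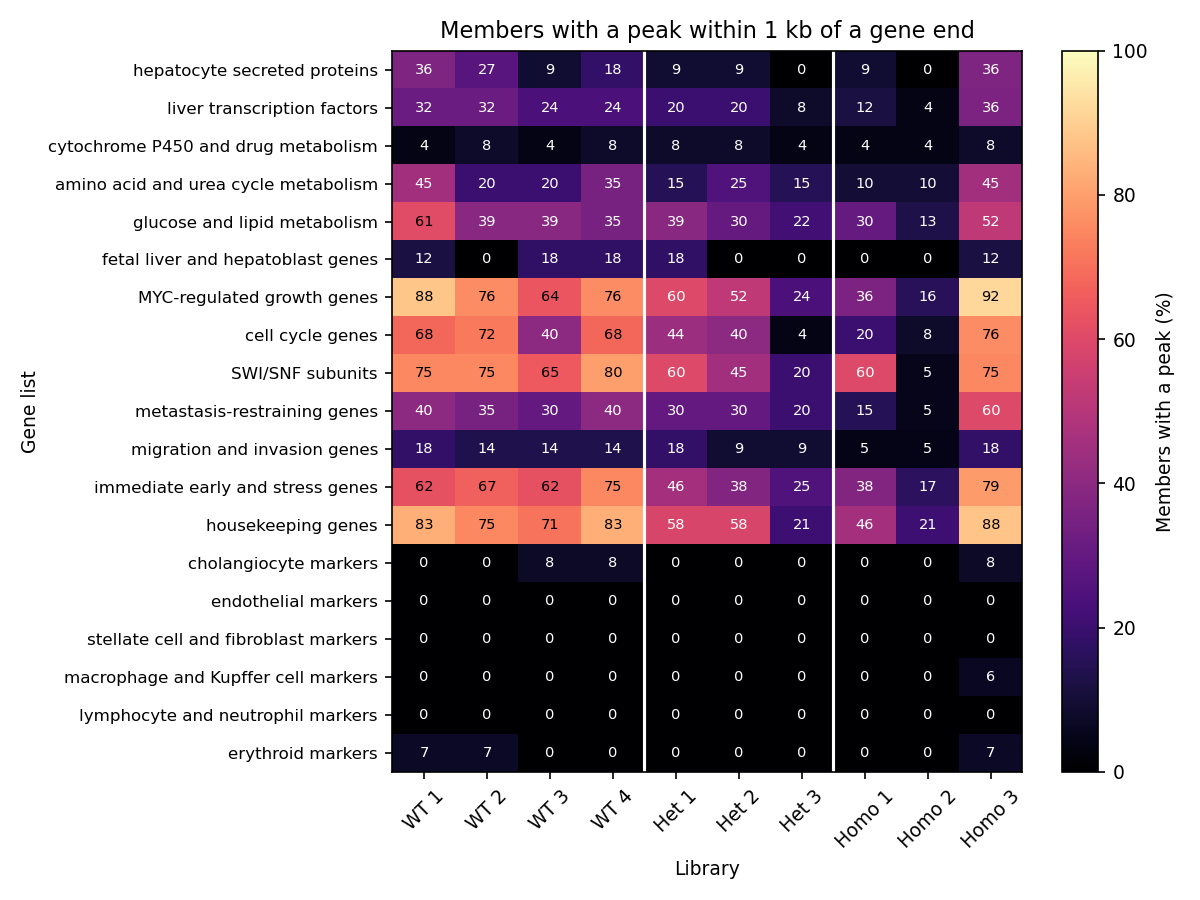
Percent of the members of each fixed gene list with a peak within 1 kb of a gene end, by library, with white lines between WT, Het and Homo. Homo 3 resembles the WT columns, with 92% of the MYC-regulated growth genes against 64% to 88% in WT, and Homo 2 has 16%.

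Between Homo and WT, none of the 19 lists differed, by count or relative to other genes, after adjustment (smallest adjusted exact permutation p = 0.724 by count). By count 0 lists had an unadjusted p under 0.05, and relative to other genes 1 list, the macrophage markers, whose members were at 0 in all WT libraries. The MYC-regulated growth genes had 19 ± 2.45 members with a peak in WT (SD, n = 4) and 12 ± 9.85 in Homo (n = 3, exact permutation p = 0.286). Ncl and Hk2 were called in 4 of 4 WT and 1 of 3 Homo libraries. The cell cycle genes had 15.5 ± 3.70 and 8.67 ± 9.07 (exact permutation p = 0.257), with Ccnb1, Ccne1 and E2f1 at 4 of 4 and 1 of 3. For the SWI/SNF subunits the values were 14.8 ± 1.26 and 9.33 ± 7.37 (exact permutation p = 0.114), with Smarcb1, Brd7 and Bcl7b at 4 of 4 and 1 of 3. Metastasis-restraining genes had 7.25 ± 0.957 and 5.33 ± 5.86 (exact permutation p = 0.571), where Cd82 was at 4 of 4 and 1 of 3, while Mat1a and Brms1 were called in Homo 3 and in no WT library. Migration and invasion genes had 3.25 ± 0.5 and 2 ± 1.73 (exact permutation p = 0.229), with Zeb1 at 3 of 4 and 1 of 3 and Snai1 at 4 of 4 and 2 of 3. The liver transcription factors Foxa3, Ppara and Nfib were at 4 of 4 and 1 of 3, as were the apolipoprotein gene Apoa2 and Fah, an enzyme of tyrosine breakdown. Among glucose and lipid genes, Cpt2 was at 3 of 4 and 1 of 3, and among immediate early genes Fosb, Atf3, Klf4 and Ddit3 were at 4 of 4 and 1 of 3. The housekeeping genes Sdha and Psmb2 had the same 4 of 4 and 1 of 3. In each of these genes with 1 Homo library, that library was Homo 3.

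Between Het and WT, 5 lists had an unadjusted exact permutation p of 0.0286 by count, each with an adjusted p of 0.109, so 0 of 19 passed. They were housekeeping genes (18.8 in WT and 11 in Het), MYC-regulated growth genes (19 and 11.3), immediate early and stress genes (16 and 8.67), SWI/SNF subunits (14.8 and 8.33) and liver transcription factors (7 and 4). With lists of equal depth 0 of 19 lists had an unadjusted p under 0.05 by count (smallest exact permutation p = 0.114). Relative to all other genes of the same library none of these 5 had p under 0.05, with log2 differences of 0.05, 0.12, 0.04, 0.02 and 0.11. The relative test gave an unadjusted p under 0.05 for 7 other lists (adjusted 0.0776), of which endothelial, stellate cell, lymphocyte and macrophage markers had 0 members with a peak in both groups, so that the added 0.5 sets their ratio. The remaining 3 were the P450 genes (1.5 and 1.67 members, log2 difference 1.05), the metastasis-restraining genes (7.25 and 5.33, 0.50) and the migration genes (3.25 and 2.67, 0.63), each with a higher relative share in Het. Members at 4 of 4 WT and 1 of 3 Het libraries included Nop2, Mcm5, Smarca4, Klf6, Gadd45b, Map2k4, Foxa3, Nfib and Fah. Fn1, encoding fibronectin, and the fetal gene Lin28b were each called in 1 of 3 Het and 0 of 4 WT libraries.

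The remaining lists had, in WT, Het and Homo, means of 5, 1.33 and 3.33 secreted protein genes (Apoa1 in 2, 0 and 0 libraries), 6, 3.67 and 4.33 amino acid genes (Ass1 in 2, 0 and 1), 10, 7 and 7.33 glucose and lipid genes, and 2, 1 and 0.667 fetal liver genes. Cholangiocyte and erythroid markers each had 0.5, 0 and 0.333. Homo means of the other lists were 4.33 for liver transcription factors, 1.33 for P450 genes, 10.7 for immediate early genes and 12.3 for housekeeping genes. Between Homo and Het 0 of 19 lists passed and 0 had an unadjusted p under 0.05, by count or relative to other genes (smallest exact permutation p = 0.3, where 0.1 is the smallest possible).

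The trend over 0, 1 and 2 floxed alleles exposed to Cre passed the adjusted threshold for 0 of 19 lists by count (0 at an unadjusted p under 0.05). Relative to other genes 0 lists passed (1 unadjusted, the macrophage markers). Without Homo 3, 6 lists passed by count: the MYC-regulated growth, cell cycle, immediate early, metastasis-restraining, housekeeping and liver transcription factor lists, with adjusted exact permutation p from 0.0302 to 0.0452. The housekeeping genes were among them, and the number of all genes with a gene-end peak was 7059 ± 720 in WT, 3929 ± 1511 in Het and 4309 ± 3356 in Homo.

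Libraries of a genotype were compared with each other and with the rest to ask whether genotype orders the open regions. The mean Jaccard index was 0.374 within groups and 0.298 between groups, a difference of 0.0758 (exact permutation p = 0.0414, one-sided). Within groups the mean was 0.514 among WT, 0.297 among Het and 0.171 among Homo libraries. Homo 3 had a mean index of 0.548 with the 4 WT libraries and of 0.164 with Homo 1 and Homo 2. Its index of 0.611 with WT 1 was the highest of all pairs. With lists of equal depth the difference was 0.0323 (exact permutation p = 0.0762, one-sided). From the deposited lists it was 0.0267, 0.0290, 0.0474 and 0.0288 without WT 1, WT 2, WT 3 and WT 4, 0.0889 and 0.0742 without Het 2 and Het 3, and 0.0827 without Homo 2, with exact permutation p from 0.0548 to 0.204. Without Homo 3 it was 0.155 (exact permutation p = 0.00159).

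**Figure D3:**
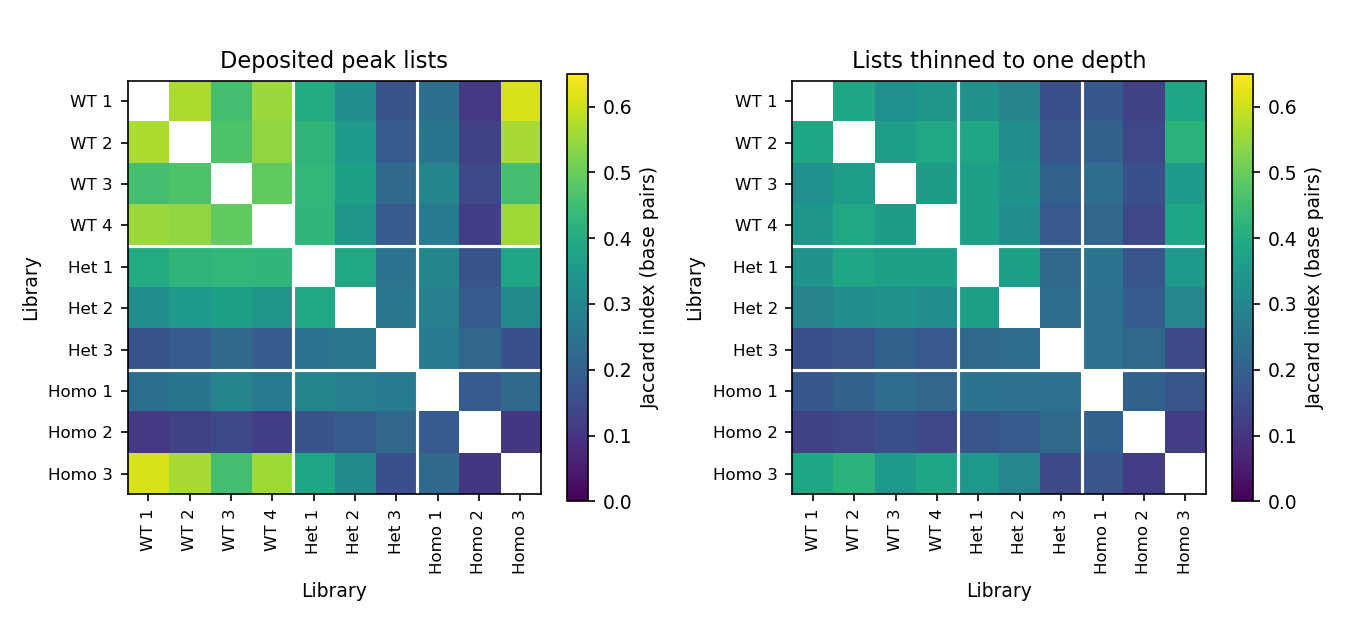
Base-pair Jaccard index for each pair of libraries, from the deposited lists (left) and after thinning to 1 depth (right), with white lines between the genotypes. The row of Homo 3 is brightest against the WT libraries in both panels, with means of 0.548 and 0.384.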

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

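In 24 measures that varied among the 4 WT libraries, each with its highest and its lowest library compared with the rest, 4 values lay so far from the others that the gap to the nearest, as a share of the whole range, passed Dixon's critical value at the 95% level. Chance gives about 1 in 20, so some of these values would arise without a cause, and none was weighed further. WT 2 kept 5887 regions after thinning to equal depth and the other 3 WT libraries 4738 to 4919. WT 1 had gene-end peaks at 14 glucose and lipid genes, against 8 to 9 in the others, and at 4 migration and invasion genes, against 3 in each of the others. WT 3 had gene-end peaks at 10 cell cycle genes and the others at 17 to 18. The groups of 3 were not tested in this way.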

How the results depend on the processing

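The lists of equal depth were chosen after seeing the data, and the other alternatives before the data were examined. Among the results that answer a comparison, 100 values under alternatives other than leaving out a library kept their direction and their side of the threshold, or stayed within 1.5 times for a count, while 17 moved further, 7 lost the threshold and 4 turned direction. Among single gene lists 250 did and 16 turned direction, all of them values that passed no test. For the named genes the share of libraries with a peak was unchanged in 182 cases and differed in 118. None turned direction, but the choice of these genes fixed this beforehand. Lists with fewer peaks leave the empty group empty, and wider windows leave the full group full. With 1748 peaks per list the differences at Nans, Capn5, Mrpl1 and Rad18 went to 0, since none of these weaker peaks was left. Wider gene windows, all sequences, deposited peaks in place of merged regions and the Jaccard index over regions turned no result that answers a comparison. Depth limits what a missing peak means, since the libraries span a 3.76-fold range of background. The motif alternatives were not run. The cause of the changes below was not tested, except where fewer libraries or thinning by construction lower what a test can reach.

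With −log10 q of at least 5, the Het minus WT difference was -4331 regions (exact permutation p = 0.0571) and -1.98 Mb (exact permutation p = 0.0571), the gene-end share difference turned to -0.147, and 24 regions separated Homo and Het. With 1748 peaks per list, the gene-end share differences turned to -1.61 for Het minus WT and 0.248 for Homo minus Het. The region counts were 18 WT-only and 7 Homo-only, 34 WT-only and 32 Het-only, and 7 and 1 for WT against both other groups, and the similarity difference was 0.0212 (exact permutation p = 0.103). Homo minus WT turned to 0.167 genes for secreted proteins, 0.417 for P450, migration and immediate early genes, 0.5 for SWI/SNF subunits and 0.583 for housekeeping genes. Het minus WT turned to 0.167 for secreted proteins and SWI/SNF subunits, 0.667 for cell cycle, 0.583 for metastasis-restraining and 0.417 for migration genes.

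With the gene body and 10 kb on each side, the macrophage list turned to -0.25 for Homo minus WT and the P450 list to -2.33 for Het minus WT. With regions built from summits, 62 were WT-only against Homo. With 50% of a region covered, 54 were WT-only against Homo, 782 WT-only and 0 Het-only between Het and WT, and 25 separated Homo and Het. At equal depth the Het minus WT difference was -1250 regions (exact permutation p = 0.2) and Homo minus Het turned to -458. The region counts were 125 WT-only and 8 Homo-only, 90 WT-only and 18 Het-only, and 105 between Homo and Het, with a similarity difference of 0.0323 (exact permutation p = 0.0762). The amino acid list turned to 0.333 for Homo minus WT, and the metastasis-restraining and migration lists to 1.08 and 0.583 for Het minus WT.

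With the replicate number as a block (replicate block), the Het minus WT difference was -3856 regions and -1.80 Mb, each with an exact p of 0.25, the smallest that 3 pairs allow, so this says nothing about stability. Libraries with the same number did not deviate together (correlations of -0.141 to 0.0139 over 9 pairs, and -0.0696 to 0.117 over 24 pairs with other numbers). These values gave no sign of pairing by number, but so few pairs cannot exclude it.

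Leaving out 1 library at a time kept 173 such values, and the others gave these ranges. Het minus WT ran from -4651 to -3045 regions and from -2.14 to -1.56 Mb; leaving out a WT or Het library gave exact p of 0.0667 or 0.1, the smallest those sizes allow. Homo minus WT ran from -5470 to -1550.5 regions and from -2.37 to -0.537 Mb, the ends being without Homo 3 and without Homo 2. Homo minus Het ran from -1543 to 2377 regions and from -0.496 to 1.33 Mb. The slopes ran from -2878 to -1153 regions and from -1.27 to -0.461 Mb per allele, the steepest without Homo 3 (exact permutation p = 0.00397 for each), and the gene-end share slope from -1.66 to 0.0676, positive without Homo 2. Region counts ran from 35 to 2103 and 2 to 30 for Homo against WT, 498 to 1258 and 1 to 10 for Het against WT, 40 to 338 for Homo and Het, and 17 to 361 and 0 to 1 for WT against both. The similarity difference ran from 0.0267 to 0.155. Between 0 and 6 gene lists passed the trend, 6 without Homo 3, and the metastasis-restraining list ran from -5.25 to 0.25 genes for Homo minus WT.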

Other observations

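All tests of explanations and of other splits in this part were chosen after the result was seen. Across the 377 members of the fixed gene lists, 11 had a gene-end peak in all 10 libraries. They were Cebpb, Glul (glutamine synthetase), Fasn and Acaca of fatty acid synthesis, Npm1 and Eif4a1 of ribosome production and translation, the cyclin gene Ccna2, Pbrm1 (a subunit of the PBAF form of SWI/SNF), the immediate early genes Jun and Btg2, and the elongation factor gene Eef1a1. Another 200 members had no gene-end peak in any library. Of the 647 regions called in all 10 libraries, 62.3% lay at gene ends, against 43.2% of the regions called in 1 library and 70.1% to 79.5% of all regions in the list of each library.

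Each of the 3 Het libraries and Homo 1 and Homo 2 had fewer regions than any WT library. Thinned to equal depth, Het 3 kept 2056 regions, Homo 1 2709 and Homo 2 1748, all below 4189, the lowest WT library (4707) less 1 WT SD, which argues against depth as the whole cause in these 3 libraries. Het 1 kept 5236, inside the WT range, so lower depth could account for its shorter list, while Het 2 kept 4242, between the bounds, and stays open. Lower signal over background in Het 3, Homo 1 and Homo 2 cannot be told apart from a loss of open regions, because the medians of pileup over background, up to 23.7 in Homo 2 and 17.2 to 21.3 in WT, come from regions that had to be called in every library. Arid1a genotype, Cre and age, which change together, also stay open and were not tested.

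Homo 3 shared more of its peaks with WT libraries than with Homo 1 and Homo 2. List length alone is argued against, since with equally long lists its lowest Jaccard index with a WT library was 0.276 and its highest with Homo 1 or Homo 2 was 0.154, while depth alone stays open, because list length caps the index at equal depth at 0.183 with Homo 2 and 0.364 with Homo 1 (observed 0.119 and 0.173), close to or below the 0.349 it would have to reach. In lists equal in depth, number and width all indices were lower and the gap was smaller. The lowest index with a WT library, 0.127, stayed above the highest with Homo 1 or Homo 2, 0.110, as it did in 20 of 20 draws. This argues against depth and length together as the whole cause. The gap does not measure their share, since the mean index among WT libraries also fell in these lists, from 0.514 as deposited to 0.139. Lower signal in Homo 1 and Homo 2 was not tested and stays open, and so does a swap of labels with a WT library. In these lists the lowest index between WT libraries, 0.128, lay below their highest with Homo 1 or Homo 2, 0.134. With equally long lists of unequal depth the order was the reverse, at 0.275 and 0.227. A single wrong label cannot be told apart from a tumour that kept WT-like chromatin: Homo 3 has the peak inside Arid1a that Homo 1 and Homo 2 lack, but given the share of WT regions each holds, both would lack such a region with a chance of 0.347, and the floxed part is not given in the sources used here.

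The 5 strongest regions of Homo 2 had nearly equal summit pileups in all 10 libraries, for example 326 to 382 tags at chromosome 9, 35305144 to 35305665, and 280 to 303 at chromosome 12, 3109790 to 3110181. The largest ratio of highest to lowest pileup was 1.19, against 3.76 for the backgrounds. A ceiling on tags per position, as removal of duplicate reads would give, may account for this. Pileups at such regions then say little about the amount of open chromatin, and no biological explanation was tested.

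Other splits of the same libraries were set beside the region counts. For WT-only against Het, the deposited lists gave 498 regions against at most 272 in another split. Only 1 of 35 splits gave as many, a share under 0.05 but the smallest possible, and not adjusted for the other counts. Being the smallest possible and unadjusted, this share does not exclude chance. List length, which by itself favours this split, is a separate limit, as every Het list was shorter than every WT list. At equal depth chance cannot be excluded either, with 90 against 135 (6 of 35). For WT-only against Homo chance cannot be excluded, with 35 regions against 765 (7 of 35 splits), nor at equal depth, with 125 against 249 (5 of 35). A split with 765 regions, many times the real count, shows that this count depends strongly on which libraries are grouped. Without Homo 3, which had the longest list, the 35 became 2103. Uneven list lengths could therefore contribute, but the source was not tested. Chance cannot be excluded for the 2 Homo-only regions (highest other 442, 28 of 35), the 1 Het-only region (477, 34 of 35), the 16 WT-only regions against both other groups (80, 8 of 100) or the 0 in the reverse pattern (438, 100 of 100). For Homo against Het the 10 splits are too few, with 40 regions and a highest other of 839, and 9 splits gave as many.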
